A study of Margaritifera margaritifera with 32 samples.

How the data were processed

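RNA from the kidney of 32 freshwater pearl mussels was sequenced as TruSeq RNA v2 libraries, one per animal. The animals came from 2 sites of the Dronne River, upstream and downstream of a dump, in 2 years, with 8 animals in each of the 4 groups. The labels also give an age class for each animal and, in the library names, a sequencing lane. Those names also hold an index sequence and a sample number. Each group had its own index sequences and each year its own range of sample numbers. An effect of either therefore cannot be told apart from that of site or year. The 4 lanes each held 8 libraries, spread over the groups.

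The deposited table holds raw read counts per assembled contig for each library, as whole numbers. The submitters' processing notes list BWA 0.7.12 and SAMtools 1.1. They do not state the assembler, the source of the contig names, or how a read matching several contigs was counted. No contig sequences or lengths came with the table. The table held 51392 contigs. Of these, 31435 carried a running number alone, 15587 a LOC number, 2962 another locus tag and 1408 a gene or protein name. The 1408 named contigs carried 1050 distinct names and held 10% of all counts. A name states a best match and not a tested identity. Numbered names such as SODC.1.3 are separate contigs under 1 name, and reads could be split between them where copies are alike.

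Counts were analysed in R 4.3.3 with edgeR 4.0.16. Contigs were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 51264 contigs, 1402 of them named. Libraries were scaled by TMM factors. One quasi-likelihood model with 4 group means was fitted to all 32 libraries (robust glmQLFit), and contrasts were tested with glmQLFTest. A contig was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were downstream against upstream in each year and over both years, 2010 against 2009 at each site, and the site by year interaction. Old were compared with young animals in a model with group and age class as additive terms. Levels are given as CPM, counts scaled to the TMM-adjusted library size, with the SD over the 8 animals of a group. Changes are log2 values with the standard error of the fitted coefficient, computed from the F statistic.

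Design, alternatives, the definitions of the gene lists and the rule for named genes were fixed before the data were examined. The lists were turned into contig names from the names alone, before any test. Definitions of metallothioneins, gonad, digestive gland, algae and parasites matched no name, which left 20 lists. Lists with at least 5 tested contigs were compared with all other contigs by camera of limma 3.58.1, on log2 CPM with a prior count of 2, with a preset correlation of 0.01 and, as an alternative, an estimated one. Camera p-values were adjusted over the lists of a comparison. Fry was run beside camera on the same lists, and its p-values are directional and not adjusted. The rule for named genes took, per comparison, the 10 higher and the 10 lower called names of largest change. Each needed a mean of at least 5 CPM in the higher group and, where a group was set against a group, 7 of its 8 libraries above the median of the lower group. It added up to 4 called members of each list of smallest p, and superoxide dismutase whatever its p. No contig was named for catalase.

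The alternatives were RLE size factors, no filter, a filter of at least 1 CPM in 8 libraries, age class, lane or both as added terms, only the groups compared, limma-voom with sample weights, DESeq2 1.42.0, subsets by age, and each of the 32 libraries left out in turn. A fit without downstream 2009 replicates 7 and 8 together, which have the lowest scaling factors, was added after the data were examined, as was the comparison of the year effects between the sites. Random splits of the animals were fitted 100 times for site, 100 times for year and 50 times for age. Correlations of fewer than 10 values were tested over all pairings, others with 1e+05 permutations, two-sided.

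The tests were run on simulated tables, each with 200 contigs changed, 100 of them 2-fold and 100 of them 4-fold. The changed libraries were those of 1 group, of both downstream groups for the mean over both years, and of the old animals for age. In the table changed downstream in 2009 the ribosomal protein contigs were also lowered 2-fold. edgeR recovered 23 and 68 of these for the site effect 2009, 19 and 78 for the site effect 2010, and 59 and 92 for the mean over both years. It recovered 22 and 80 for the year effect upstream, 19 and 71 for the year effect downstream, 5 and 46 for the interaction, and 17 and 74 for age. For the site effect 2009 DESeq2 recovered 37 and 80, and limma-voom 26 and 71. Unchanged contigs called there were 22 by DESeq2, 5 by limma-voom and 5 by edgeR. Contigs were drawn independently in the simulated tables, so these rates do not cover outlying animals or variation shared by contigs. Total counts per library ran from 55.7 to 190 M. A floor of 3 counts corresponds to between 0.0116 and 0.0825 CPM per library. Such floors cover counting error alone, since reads without molecular identifiers are not independent molecules. All 32 columns of the table were used.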

Results

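Kidney transcripts were measured by RNA sequencing in 32 freshwater pearl mussels (Margaritifera margaritifera), a long-lived river bivalve. The title of the series names trace metal contamination as its subject, and the sites lie above and below a dump. Each of the 4 groups held 8 animals. Total counts averaged 99.3 ± 35.9 M (SD, n = 8) upstream in 2009, 79.9 ± 19.0 M downstream in 2009, 76.2 ± 10.0 M upstream in 2010 and 101.7 ± 41.6 M downstream in 2010, with 55.7 M in the shallowest library and 190 M in the deepest. The animals comprised 10 young, 11 middle-aged and 11 old ones. The age classes were spread unevenly: 7 of 8 animals downstream in 2009 were old, against 1 of 8 upstream in 2009, 1 upstream in 2010 and 2 downstream in 2010.

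The libraries differed widely within groups, with correlations of log2 CPM between libraries of a group from 0.618 to 0.974 and a common biological coefficient of variation of 55.3%. The first principal component held 35.8% of the variance and the next 15.4%. Downstream 2009 replicates 7 and 8 lay at its far end, at 242 and 383, and had the lowest scaling factors, 0.503 and 0.524. Contigs named for ribosomal proteins summed to 110000 and 94500 CPM in these animals, against 15600 to 31900 CPM in the other downstream animals of 2009.

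**Figure D1:**
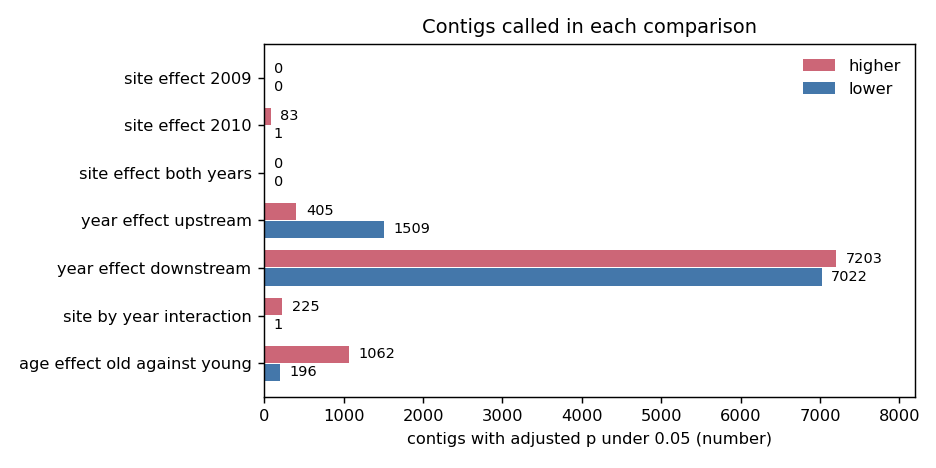
Number of contigs with an adjusted p under 0.05 in each comparison, higher and lower drawn as separate bars from 0. The longest bars are those of the year effect downstream, 7203 higher and 7022 lower.

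The site effect in 2009 asks whether kidney transcripts differed downstream of the dump from those upstream. Cathepsin L1 (CATL1), a lysosomal protease, had 11.4 CPM upstream and 29.5 CPM downstream, a log2 difference of 1.37 ± 0.47 (SE, n = 8 per group) with an adjusted p of 0.534. The superoxide dismutase contig SODC.2.3, named for the enzyme that removes superoxide, had 1.72 ± 0.682 and 4.74 ± 3.97 CPM (SD), a difference of 1.46 ± 0.46 with an adjusted p of 0.534. DIAP2.1.3, named for an inhibitor of apoptosis, had 7.50 CPM upstream and 3.87 CPM downstream, a difference of -0.95 ± 0.22. These 3 passed when adjusted over the list alone (p of 0.0182, 0.0469 and 0.00555), which does not adjust for the number of lists. Each was the only member of its list to pass in that way. The lysosome list, which holds CATL1, summed to 18.1 ± 6.65 CPM upstream and 34.2 ± 28.6 CPM downstream (SD). Its highest sum downstream was 99 CPM. The fit had no age term, and 7 of 8 downstream animals were old, against 1 of 8 upstream. Over all contigs edgeR called 0 of 51264, with 4277 at an unadjusted p under 0.05; DESeq2 called 49 and limma-voom 0.

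The other superoxide dismutase contigs in 2009 differed by 1.12 ± 0.54 (SODC.1.3) and 1.13 ± 0.54 (SODC.3.3), each with an adjusted p of 0.596. Without downstream 2009 replicate 8 the difference of SODC.3.3 was -0.039. All 39 contigs for ribosomal proteins had estimates above 0 downstream in 2009, with a median of 0.55, and 2 of the 30 for actins and tubulins had estimates below 0, with a median of 0.63. None of either list was called, over all contigs or adjusted over the list alone. The lists ranked above other contigs by camera with the preset correlation (adjusted p of 2.09e-06 and 0.000256). They did not with an estimated correlation (adjusted p of 0.85 for each), and their fry p-values were 0.26 and 0.298. The medians were -0.49 and -0.18 without downstream 2009 replicates 7 and 8, and 0.233 and 0.481 with an age term. The medians of heat shock proteins (0.15, 8 contigs) and of the cytochrome P450 names (-0.49, 4 contigs) also came from lists with 0 called contigs. They were -0.091 and -0.479 without these 2 animals, and 0.253 and -0.231 with an age term. Median, mean and camera direction differed in sign for glutathione and redox (median -0.026, mean 0.047), for ubiquitin and proteasome (median 0.17, mean -0.021) for lysosome (median -0.49, mean 0.10) and for oxidative phosphorylation (median -0.10, camera higher).

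In 2010 the same question gave 84 contigs, 83 higher and 1 lower downstream, none of them with a gene name. Of the 84, 64 carried a running number, 18 a LOC number and 2 another locus tag, and the table does not pair these with genes. By the smallest p, contig_25228 rose from 2.83 ± 0.823 to 6.78 ± 1.14 CPM (SD, n = 8), a log2 change of 1.26 ± 0.19 with an adjusted p of 0.00688. LOC105330264.1.3 rose from 8.04 to 15.9 CPM, by 0.99 ± 0.15. LOC105325122 fell from 38.3 to 10.8 CPM, by -1.83 ± 0.40, with an adjusted p of 0.0482. The RNA helicase Ddx17 was the named contig of smallest p, with 39.7 ± 8.56 CPM upstream and 82.6 ± 24.1 CPM downstream, a difference of 1.06 ± 0.25 and an adjusted p of 0.0642. The difference for pold4, a DNA polymerase delta subunit, was -0.81 ± 0.21 with an adjusted p of 0.0843.

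NAIP, named for an inhibitor of apoptosis, had 2.03 ± 0.573 CPM upstream and 3.76 ± 0.498 CPM downstream in 2010. Its adjusted p was 0.0859 over all contigs and 0.0221 adjusted over the list alone, the only member of any list to pass in that way. The superoxide dismutase contigs differed by 0.040 ± 0.54 (SODC.1.3), 0.25 ± 0.45 (SODC.2.3) and -0.13 ± 0.54 (SODC.3.3), with adjusted p of 0.982, 0.844 and 0.940. All 11 tropomyosin contigs had estimates below 0 downstream, with a median of -0.93, and none was called; TPM.6.10 had 146 and 44.8 CPM, with an adjusted p of 0.296. With the preset correlation camera called the tropomyosins (adjusted p of 0.0128), the 19 ubiquitin and proteasome contigs (median -0.25, 0.000656) and the 41 contigs for inhibitors of apoptosis and caspases (median -0.22, 0.0142). With an estimated correlation the adjusted p-values were 0.665, 0.656 and 0.665, and fry gave p of 0.256, 0.0593 and 0.291. Signs differed for ribosomal proteins (median -0.030, mean 0.22), translation factors (median -0.23, mean 0.20) and viruses and mobile elements (median -0.10, camera higher).

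The count for 2010 moved with the setting and the library. DESeq2 called 755 contigs, limma-voom 14879, and edgeR 29 with RLE factors, 39 with a lane term, 35 with age and lane terms, 1487 with only the 2 groups and 782 without downstream 2009 replicates 7 and 8. Without upstream 2009 replicates 2, 3, 4, 5 and 7 in turn it was 32, 28, 30, 27 and 33, and without downstream 2009 replicates 1, 3, 4, 5, 6, 7 and 8 it was 33, 33, 35, 41, 39, 151 and 556. Without upstream 2010 replicates 1 to 8 in turn it was 20, 20, 16, 258, 26, 23, 24 and 40, and without downstream 2010 replicates 1, 2, 3, 5, 6, 7 and 8 it was 33, 30, 23, 233, 26, 24 and 24.

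Over both years, the mean site effect named EGLN1.1.2, an oxygen-sensing prolyl hydroxylase, as the named contig of smallest p, with a difference of -0.75 ± 0.20 and an adjusted p of 0.317. Its means were 5.64 CPM upstream and 2.84 CPM downstream in 2009, and 3.86 and 2.71 CPM in 2010. CP3A4, a cytochrome P450, differed by -0.85 ± 0.31 and passed adjusted over the list alone (p of 0.0420), as did CATL1 (0.73 ± 0.33) and the thioesterase ppt2 (-0.44 ± 0.19), each with 0.0475. The differences of SODC.1.3, SODC.2.3 and SODC.3.3 were 0.58 ± 0.38, 0.85 ± 0.32 and 0.50 ± 0.38, with adjusted p of 0.523, 0.326 and 0.590. Ribosomal protein contigs had a median of 0.24 and were called by camera with the preset correlation (adjusted p of 0.0229) and not with an estimated correlation (adjusted p of 0.933). That median was -0.274 without downstream 2009 replicates 7 and 8 and -0.00639 with an age term. For this list fry gave p of 0.406 in the main fit. Signs differed for translation factors (median -0.048, mean 0.26), immune recognition (median -0.11, mean 0.089) and ABC transporters (median -0.031, camera higher). edgeR called 0 of 51264 contigs over both years, with 6429 at an unadjusted p under 0.05; DESeq2 called 227 and limma-voom 0.

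Site effects of the 2 years share no library. Across contigs, which are not independent replicates, their log2 values had a Pearson r of 0.192 and a Spearman rho of 0.146, and the sign was shared by 56.1% of contigs. The jackknife standard error of r over the 32 libraries was 0.295, and with an age term r was -0.057.

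Between 2009 and 2010 upstream, SQRDL, a mitochondrial enzyme of sulfide oxidation, rose from 32.6 ± 8.07 to 80 ± 17.6 CPM (SD, n = 8), a log2 change of 1.30 ± 0.20 with an adjusted p of 0.000495. ES1 fell by 1.85 on the log2 scale, from 22.5 ± 9.06 to 6.25 ± 1.23 CPM, with an adjusted p of 0.00014. The fibrinogen-domain contig FBCDA fell from 23.6 ± 14.1 to 8.46 ± 1.98 CPM, by -1.48 ± 0.30, and NDUFA5, a subunit of respiratory complex I, fell from 3.24 to 1.17 CPM, by -1.46 ± 0.27. These 4 were called in all 10 alternatives and with each of the 32 libraries left out, and all 8 libraries of the higher year lay above the median of the lower year. In all, edgeR called 405 contigs higher and 1509 lower in 2010, among them 10 and 120 named ones.

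Contigs that also fell upstream were the guanylate-binding proteins GBP1 (-2.23 ± 0.61, from 12.5 to 2.66 CPM) and GBP3 (-1.91 ± 0.53), and RSAD2.1.2, named for viperin (from 16.1 ± 24.3 to 4.03 ± 2.54 CPM). Their adjusted p-values of 0.0340, 0.0370 and 0.0372 lay near the threshold. They passed in neither limma-voom nor the fits with an age term, and without upstream 2009 replicate 3 they rose to 0.158, 0.184 and 0.301. The contig RhPVgp2, placed by its name in the list of viruses and mobile elements, fell by 9.75 on the log2 scale with a standard error of 1.54 and an adjusted p of 0.00063. Its median was 11.6 CPM upstream in 2009 (0.0335 to 138 CPM) and 0.0372 CPM in 2010, when 25 reads were counted over the 8 libraries. It did not pass with limma-voom. The plasminogen-named plg.3.3 fell by 8.77, which rested on upstream 2009 replicate 7 at 683 CPM; without that animal its adjusted p was 0.239. UBI12, a ubiquitin name at a mean of 1.83 CPM in 2009, fell by 5.11 with an adjusted p of 0.00698, and not with limma-voom. Neither passed downstream, and their interactions had adjusted p of 0.325 (plg.3.3) and 0.201 (UBI12). UBI12 was highest in upstream 2009 replicates 4 and 5, at 6.09 and 4.03 CPM. These animals also had the highest sums of the diatom-prefix contigs described below, 82.5 and 52.3 CPM. Downstream in 2009 the highest sum, 21.4 CPM in replicate 7, went with 0.137 CPM of UBI12. Whether its reads came from the mussels was not tested.

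**Figure D2:**
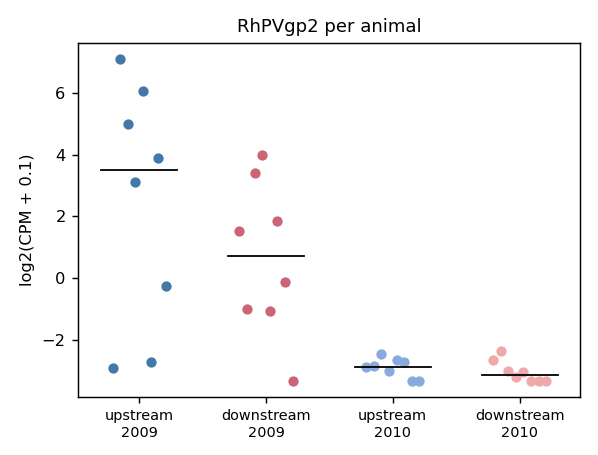
Level of the contig RhPVgp2 per animal, as log2 of CPM plus 0.1, in the 4 groups of 8 animals; points are animals and bars are group medians. The medians were 11.6 and 1.81 CPM in 2009 and 0.0372 and 0.0143 CPM in 2010.

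Among the 41 contigs for inhibitors of apoptosis and caspases, 8 fell upstream and 0 rose, or 14 and 1 adjusted over the list alone. The caspase contigs CASP2.1.6, CASP2.2.6 and CASP2.4.6 fell by 1.93, 1.92 and 1.98. Without upstream 2009 replicate 3 their adjusted p was 0.0564, 0.0685 and 0.0853. DIAP2.1.3 fell by 0.88, with an adjusted p of 0.0211, and 0.0519 without that animal. Contigs under 1 name such as these may share reads and are not separate evidence. Of 25 oxidative phosphorylation contigs 3 fell, or 19 adjusted over the list alone, with 1 higher in that count; NDUFB3 fell from 214 ± 153 to 91.9 ± 26.4 CPM (-1.22 ± 0.33), with an adjusted p of 0.0301, and 0.113 without upstream 2009 replicate 4. Of 39 ribosomal protein contigs 0 were called by edgeR and 27 were lower adjusted over the list alone, with a median of -1.19. The median of the 21 immune recognition contigs was -0.48 (1 lower, or 3 over the list alone) and that of the 28 calmodulins and carbonic anhydrases was -0.52 (0 called, 3 over the list alone). Under an age term 3 inhibitors of apoptosis and caspases, 1 oxidative phosphorylation, 0 ribosomal protein, 1 immune recognition and 0 calmodulin and carbonic anhydrase contigs fell, with medians of -0.315, -0.726, -0.957, -0.397 and -0.677, against -0.314, -0.938, -1.19, -0.477 and -0.515. In the fit without downstream 2009 replicates 7 and 8 these counts were 12, 6, 26, 2 and 2, with medians of -0.326, -0.95, -1.2, -0.492 and -0.535.

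Camera called these lists lower upstream with the preset correlation: oxidative phosphorylation (adjusted p of 6.83e-07), ribosomal proteins (1.11e-06), inhibitors of apoptosis and caspases (6e-04), immune recognition (0.00991), and shell and calcium (0.0221). With an estimated correlation each had an adjusted p of 0.562. Their fry p-values were 0.0276, 0.0727, 0.042, 0.0061 and 0.0876, in the same order. The superoxide dismutase contigs were not called, at -1.21 ± 0.54 (SODC.1.3), -0.19 ± 0.45 (SODC.2.3) and -0.73 ± 0.54 (SODC.3.3), with adjusted p of 0.213, 0.848 and 0.469. Of the 10 named contigs that rose, the rule for named genes took SQRDL and most of the others. It took DCE2, named for a glutamate decarboxylase (0.93 ± 0.24), the mitochondrial acyl carrier protein ACPM (0.86 ± 0.25), and VWA5A.1.2 and VWA5A.2.2 (0.61 ± 0.15 and 0.60 ± 0.15). It also took znf318 (0.59 ± 0.14), PPIL4 (0.52 ± 0.14) and the splicing factor U2AF2 (0.46 ± 0.13). Of these, znf318 passed with each library left out; the highest adjusted p was 0.0790 for DCE2 (without upstream 2009 replicate 4), 0.0961 for ACPM (without upstream 2010 replicate 2), 0.0529 and 0.0564 for VWA5A.1.2 and VWA5A.2.2 (without upstream 2010 replicate 4), and 0.0626 and 0.0973 for PPIL4 and U2AF2 (without upstream 2009 replicate 2). Median and camera direction differed in sign for tropomyosins (median 0.32) and for viruses and mobile elements (median -0.020). With an age term these medians were -0.069 and 0.00217.

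The total of 1914 calls upstream became 784 to 3624 with 1 library left out. It was 842, 784 and 3624 without upstream 2009 replicates 3, 4 and 8, 3071 without downstream 2009 replicate 8, and 869, 1204 and 1189 without upstream 2010 replicates 4, 5 and 7. It was 4420 without downstream 2009 replicates 7 and 8 together, and 26 ribosomal protein contigs were then lower. DESeq2 called 3612, and edgeR 1180 with only the 2 groups and 1059 with age and lane terms.

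Downstream, the year comparison had the highest count of the 7, with 7203 contigs higher and 7022 lower in 2010, among them 53 and 513 named ones. The inhibitor of apoptosis XIAP.5.6 rose from 3.02 ± 0.678 to 8.83 ± 2.05 CPM (SD, n = 8), by 1.54 ± 0.20 with an adjusted p of 6.58e-06. The RNA helicase Ddx17 rose from 31.3 ± 8.83 to 82.6 ± 24.1 CPM (1.40 ± 0.25), and the tRNA methyltransferase name TRMT44.2.2 rose from 4.55 to 16.7 CPM (1.88 ± 0.29). FBCDA fell by 1.93, from 24.5 ± 13.2 to 6.43 ± 1.26 CPM, with an adjusted p of 4.41e-05. RhPVgp2 fell by 7.37 with a standard error of 1.43; its median was 1.81 CPM in 2009 and 0.0143 CPM in 2010. These 5 were called in every alternative and with each library left out. The interaction reached an adjusted p of 0.0347 for Ddx17 and 0.0402 for TRMT44.2.2, and not for XIAP.5.6 (0.0855), FBCDA (0.841) or RhPVgp2 (0.779).

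Ribosomal protein contigs fell downstream in 31 of 39 cases, and in as many adjusted over the list alone, with a median of -1.76. RS6 fell by 1.90 (2840 ± 2810 to 761 ± 238 CPM), RL40 by 1.92 and Rpl7.1.2 by 1.84; their interactions had adjusted p of 0.779, 0.851 and 0.799. Of 8 translation factors 6 fell, such as EF1A.2.2, which carries aminoacyl-tRNA to the ribosome (-1.52 ± 0.37, from 9760 to 3400 CPM). Oxidative phosphorylation had 12 of 25 lower, or 19 adjusted over the list alone, such as NDUFA11 (-1.24 ± 0.29) and the ATP synthase subunit atp5o.1.2 (-1.33 ± 0.35). Cytoskeletal names had 14 of 30 lower, or 22 adjusted over the list alone, among them the actin ACT2 (-1.74 ± 0.49) and the tubulin TBA3.2.3 (-1.85 ± 0.42). Without downstream 2009 replicates 7 and 8, which had the highest ribosomal sums of their group, 1 ribosomal protein contig was lower (median -0.792), as were 0 translation factors (-0.464), 4 oxidative phosphorylation (-0.591) and 1 cytoskeletal contigs (-0.567). With an age term 16 ribosomal protein, 2 translation factor, 7 oxidative phosphorylation and 3 cytoskeletal contigs were lower. The medians of these 4 lists were then -1.43, -0.745, -0.904 and -1.2, against -1.76, -0.921, -0.933 and -1.49 without that term.

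**Figure D3:**
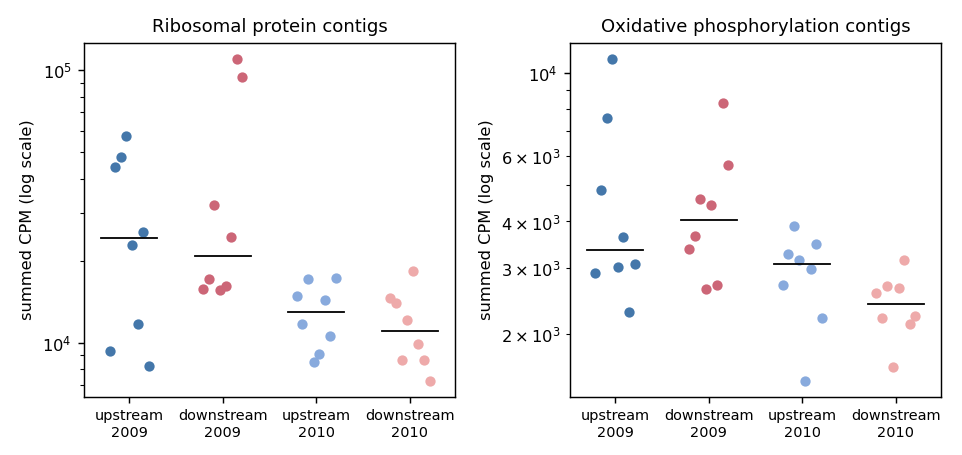
Summed CPM per animal, on a log axis, of the contigs named for ribosomal proteins and for oxidative phosphorylation, in the 4 groups of 8 animals; points are animals and bars are group medians. Ribosomal sums reached 110000 CPM in downstream 2009 replicate 7 and lay between 7270 and 18400 CPM in the animals downstream in 2010.

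Among redox and metal names, SODC.1.3 fell downstream by 2.29, from 27.5 ± 25.2 to 5.62 ± 1.98 CPM, SODC.3.3 by 1.98, from 6990 ± 11200 to 1770 ± 710 CPM, and SODC.2.3 by 1.41, with adjusted p of 0.0031, 0.0083 and 0.0216. Without downstream 2009 replicate 8 the adjusted p of SODC.3.3 was 0.133, and without replicate 7 that of SODC.2.3 was 0.0735. Of 14 glutathione and redox contigs 6 fell, or 8 adjusted over the list alone. Of 8 metal transport and storage contigs 4 fell: the ferritins FRIS.1.2 (-1.39 ± 0.38, from 20100 to 7660 CPM) and FRIS.2.2 (-1.54 ± 0.41), and the zinc transporters slc30a8.2.3 and slc30a8.3.3 (-0.77 ± 0.27 and -0.74 ± 0.27). The zinc transporters had adjusted p of 0.0335 and 0.0387, and 0.0749 and 0.0978 without downstream 2010 replicate 8 and downstream 2009 replicate 2. Without downstream 2009 replicates 7 and 8, 2 contigs of each list were lower, and with an age term 2 of each. The medians were -0.811 for glutathione and redox and -0.805 for metals, -0.552 and -0.85 without the 2 animals, and -0.932 and -0.734 with an age term. The ABC transporter list had 2 of 5 higher, MRP3.1.2 (1.26 ± 0.28) and MRP4 (0.78 ± 0.28), and 0 lower, with a median of 0.646. This was 0.298 without the 2 animals and -0.294 with an age term, with 1 contig higher in each. The adjusted p of MRP4 was 0.0364, and 0.0860 without downstream 2010 replicate 3.

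Of the 41 inhibitors of apoptosis and caspases, 3 rose downstream and 18 fell, or 3 and 20 adjusted over the list alone. Those that rose were XIAP.5.6, Xiap (1.54 ± 0.22) and NAIP (1.26 ± 0.23). Immune recognition had 9 of 21 lower and 1 higher, or 10 and 1 adjusted over the list alone, with falls of myd88 (-0.86 ± 0.18), an adaptor of Toll-like receptors, and of the ficolin FCN1.1.2 (-1.95 ± 0.52), whose adjusted p was 0.0919 without downstream 2009 replicate 8. The chaperones had 4 of 8 lower, or 6 over the list alone, among them GRP78 (-0.93 ± 0.30), and ubiquitin and proteasome 9 of 19, in both counts, among them PSA6 (-1.34 ± 0.33). Among the 28 calmodulins and carbonic anhydrases 6 fell, such as CALM3.1.2 (-2.17 ± 0.48). Smaller lists had 3 of 4 integrins and peroxidasin lower (hemocyte markers), 2 of 11 tropomyosins, and 1 each of 3 cilia, 3 lysosome and 4 DNA repair contigs. Of 4 cytochrome P450 and 2 glycolysis and TCA contigs edgeR with 4 group means and DESeq2 called 0. limma-voom called 1 cytochrome P450, and edgeR with an age term 1 glycolysis and TCA contig, lower, with a list median of -1.17 against -0.629. Among the 10 viruses and mobile elements 3 rose and 2 fell, with a median of -0.30 and camera higher. Several of these counts were lower in the fit without downstream 2009 replicates 7 and 8, with 12 inhibitors of apoptosis and caspases, 6 immune recognition, 1 chaperone, 5 ubiquitin and proteasome, 2 calmodulin and carbonic anhydrase, 1 hemocyte and 0 tropomyosin, cilia, lysosome and DNA repair contigs falling. The medians of the first 6 of these lists were -0.544, -0.862, -0.799, -0.742, -0.856 and -0.957, and in that fit -0.481, -0.815, -0.412, -0.453, -0.328 and -0.788. With an age term 6, 5, 1, 4, 2 and 2 of the first 6 lists fell, with medians of -0.599, -1.01, -0.597, -0.603, -0.727 and -0.845, as did 5 tropomyosins (median -1.41, against -1.23) and 0 cilia, lysosome and DNA repair contigs.

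After RhPVgp2, kielin/chordin-like contigs had the largest falls among the called contigs of the rule for named genes downstream, with kcp at -3.51 ± 0.91 (595 ± 1030 to 52.2 ± 24.2 CPM), KCP.2.2 at -3.43 ± 0.93 and KCP.1.2 at -3.27 ± 0.95. In downstream 2009 replicate 7 kcp stood at 3130 CPM. Without that animal the adjusted p was 0.067 for KCP.2.2 and 0.128 for KCP.1.2, and without replicates 7 and 8 together none of the 3 passed. The complement factor properdin (cfp, -2.37 ± 0.54), klf11 (-2.26 ± 0.53) and the purine synthesis enzyme PUR9.1.2 (-2.38 ± 0.69) fell too and lost their calls in that fit; PUR9.1.2 also did without replicate 8 alone (adjusted p of 0.152). The splicing factors u2surp and SRSF4 rose by 1.88 ± 0.36 and 1.12 ± 0.21, while of 17 splicing names 3 rose and 5 fell. Also higher were pogk.7.8 (1.43 ± 0.21) and the retrotransposon name LIN1.1.2 (1.37 ± 0.25).

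Camera with the preset correlation called 12 lists lower downstream, with adjusted p-values from 2.3e-08 for ribosomal proteins to 0.0271 for glutathione and redox. With an estimated correlation none was called. The adjusted p was then 0.269 for 9 of them, 0.279 for shell and calcium, 0.342 for cytoskeleton and 0.416 for tropomyosins. The fry p-values of the 12 lists ran from 0.000295 for immune recognition to 0.0885 for tropomyosins, with 0.00718 for ribosomal proteins. The total count was 8298 with an age term, 5446 with age and lane terms and 24469 with limma-voom, and 10692 without downstream 2009 replicates 7 and 8.

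Year effects of the sites use separate libraries. Called in both were 277 higher contigs, against 56.9 expected if the calls were independent, and 1183 lower ones, against 207 expected. In opposite directions 5 were called. Both contrasts came from the same fit, with a shared dispersion per contig, and contigs are not independent. The expected counts are therefore a reference and not a test. Of the 130 named contigs called upstream, 105 were lower at both sites, 5 higher at both and 1 opposite. FBCDA (-1.48 and -1.93) was among the lower ones. Across contigs, which are not independent replicates, the log2 values had a Pearson r of 0.638, with a jackknife standard error of 0.136 over libraries, and a Spearman rho of 0.68.

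**Figure D4:**
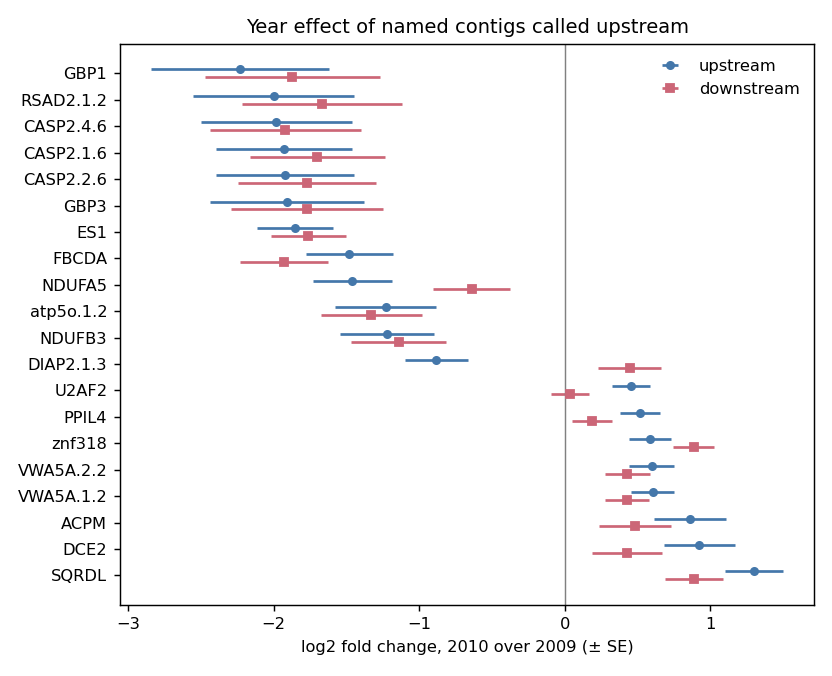
Log2 change from 2009 to 2010 with its standard error, upstream (circles) and downstream (squares), of named contigs called upstream, 8 animals per group; superoxide dismutase, the contigs with changes beyond -5 and some others are left out. SQRDL lies at 1.30 upstream, and ES1 at -1.85.

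The site by year interaction tests whether the site effect differed between the years. NHRF1, a scaffold protein of membrane transporters, had 14.7 ± 7.77 CPM upstream and 5.53 ± 3.06 CPM downstream in 2009 and 6.67 ± 1.47 and 10.7 ± 2.94 CPM in 2010 (SD, n = 8), an interaction of 2.09 ± 0.46 with an adjusted p of 0.0347. Ddx17 had 44.3 and 31.3 CPM in 2009 and 39.7 and 82.6 CPM in 2010 (1.56 ± 0.34). TRMT44.2.2 (1.75 ± 0.40) and DIAP2.1.3 (1.33 ± 0.31) changed in the same sense, and ppp1r15b, a regulatory subunit of protein phosphatase 1, in the opposite one (-0.79 ± 0.18), from 3.89 and 5.65 CPM to 3.80 and 3.19 CPM. ADHX.4.4 (1.30 ± 0.28) lay outside the rule for named genes, at 4.78 CPM, and was chosen after its values were seen. edgeR called 226 contigs, 225 with a higher and 1 with a lower site effect in 2010, 6 of them named.

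The interactions of SODC.1.3, SODC.2.3 and SODC.3.3 were -1.08 ± 0.76, -1.21 ± 0.64 and -1.25 ± 0.76, with adjusted p of 0.718, 0.517 and 0.624. Among the lists, inhibitors of apoptosis and caspases had 1 contig called, or 3 adjusted over the list alone. Camera with the preset correlation called cytoskeleton (median -0.94), tropomyosins (-1.54), ubiquitin and proteasome (-0.43), heat shock and chaperones (-0.46) and ribosomal proteins (-0.63). The adjusted p with an estimated correlation was 0.441 for the first 4 and 0.539 for ribosomal proteins. Fry p-values of the 5 were 0.276, 0.266, 0.0914, 0.0476 and 0.457. In the fit without downstream 2009 replicates 7 and 8 the medians of the 5 were -0.0642, -0.735, -0.219, -0.137 and 0.38. All 5 named contigs of the rule lost their calls with an age term, with a lane term and with both, and with between 16 and 24 of the 32 libraries left out in turn. The highest adjusted p was 0.071 for NHRF1 and 0.0738 for Ddx17.

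The interaction count was 137 with RLE factors, 37 with an age term, 93 with a lane term, 67 with both terms, 940 with DESeq2, 4070 with limma-voom and 706 without downstream 2009 replicates 7 and 8. Without upstream 2009 replicates 1, 4, 6, 7 and 8 in turn it was 36, 77, 388, 131 and 42, and without downstream 2009 replicates 3, 4, 5, 6 and 8 it was 35, 81, 129, 91 and 632. Without upstream 2010 replicates 1 to 7 it was 42, 43, 36, 633, 63, 77 and 87, and without downstream 2010 replicates 2, 3, 5, 6, 7 and 8 it was 127, 36, 840, 64, 46 and 40.

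Old animals were compared with young ones in the model with group and age terms. Downstream in 2009 there were 0 young animals and 7 of the 11 old ones, so 4 old animals shared a group with young ones. The CPM levels given here pool over the groups and so also hold differences between them. Nitric oxide synthase (NOS) was higher in old animals, by 3.80 ± 0.96 on the log2 scale (0.686 ± 1.17 CPM in 10 young and 10.9 ± 13.2 CPM in 11 old animals, SD), with an adjusted p of 0.0366. PAKG (3.46 ± 0.72), the galactosyltransferase B3GALT5 (3.12 ± 0.75), NEURM.1.2 (2.49 ± 0.68) and the histone H2A.2.2 (1.65 ± 0.44) were higher too. The collagen IV chain CO4A1 was lower, by -1.48 ± 0.41 (199 ± 148 and 81.6 ± 41.1 CPM), as were kinesin light chain (KLC, -0.99 ± 0.26), RAB10 (-0.97 ± 0.26), FKB1B (-0.85 ± 0.23) and the TGF-beta receptor TGFR1 (-0.76 ± 0.18). edgeR called 1062 contigs higher and 196 lower in old animals, 9 and 6 of them named.

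No contig of the 20 lists was called for age over all contigs. Adjusted over the list alone 5 calmodulins and carbonic anhydrases and 2 cilia contigs were higher, and 1 translation factor was higher and 1 lower. Ribosomal protein contigs had a median of 0.85, cytoskeletal contigs of 0.56 and shell and calcium contigs of 0.38, each called by camera with the preset correlation (adjusted p of 2.38e-05, 0.0408 and 0.0408) and not with an estimated correlation (adjusted p of 0.96). Fry gave p of 0.0867, 0.292 and 0.0837 for these lists. Signs differed for glutathione and redox (median 0.067, mean -0.075) and for heat shock and chaperones (median -0.088, camera higher). SODC.1.3, SODC.2.3 and SODC.3.3 differed by 0.45 ± 0.66, 0.78 ± 0.50 and -0.11 ± 0.71, with adjusted p of 0.669, 0.331 and 0.930.

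The age count rested on single libraries. Without downstream 2010 replicate 5, 1 of the 2 old animals there, it was 0, the named contigs of this comparison had adjusted p of 0.238 (TGFR1) to 0.334 (RAB10), and that of NOS was 0.283; without downstream 2010 replicates 1, 2, 7 and 8 it was 827, 2178, 36 and 133. Without upstream 2009 replicates 6, 7 and 8 in turn it was 308, 353 and 292, without downstream 2009 replicates 5 and 8 it was 2580 and 2348, and without upstream 2010 replicates 1, 4, 6 and 7 it was 775, 473, 673 and 780. It was 4335 with a lane term, 564 in the animals of 2010, 13511 with no group term, 3680 without downstream 2009 replicates 7 and 8, 4104 with DESeq2 and 8554 with limma-voom. Of the named contigs 3 passed in the animals of 2010.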

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

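The tests of the age makeup on the ratio of the year effects, and those of lane, depth and ingested or attached organisms on RhPVgp2, were chosen after the result was seen, as were the fit without downstream 2009 replicates 7 and 8 and the standard errors with an age term.

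By depth and composition, 3 libraries stood apart from the other 7 of their group by Dixon's test at the 95% level. Downstream 2009 replicate 8 had 47816 contigs detected, against 50924 to 51282. Upstream 2010 replicate 5 had a scaling factor of 1.468, against 1.001 to 1.113. In upstream 2009 replicate 7 the most abundant contig held 15.1% of counts, against 3.97 to 4.83%.

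The same test on 107 named contigs in 4 groups, 428 tests in all, marked 40 values. Chance marks about 1 in 20 groups. Of the 40, 13 lay in downstream 2010 replicate 5. There the levels were below the other animals for DIAP2.1.3 (3.24 CPM), PPIL4 (7.6), DCE2 (3.15), UBB.1.2 (372), TPM1 (2.37), SRSF4 (6.67), Ddx17 (34.4), TRMT44.2.2 (4.65), u2surp (2.35), FKB1B (1.96) and TGFR1 (5.46), and above them for MGST2 (2.47) and CFA20 (29.5). This old animal is the one without which no contig was called for age by edgeR.

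Downstream 2009 replicate 7 was far above the others for kcp (3130 CPM), KCP.2.2 (711) and KCP.1.2 (240) and below them for TRMT44.2.2 (2.12) and u2surp (0.522). Downstream 2009 replicate 8 was below for LIN1.2.2 (4.42), MRP3.1.2 (1.14) and pogk.7.8 (5.2). Downstream 2009 replicate 5 was below for CASP2.4.6 (0.904) and CASP2.1.6 (0.921) and above for POGK.4.4 (7.28). Upstream 2009 replicate 7 was above for plg.3.3 (683) and below for kcp (2.13), KCP.2.2 (0.314) and KCP.1.2 (0.165).

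Upstream 2010 replicate 5 was below for atp5o.1.2 (12.2 CPM), atp5o.2.2 (22.5), NDUFA11 (14.6), gstz1 (18) and FRIS.1.2 (4710). Upstream 2010 replicate 8 was below for SODC.1.3 (0.324) and ITB6 (0.802) and above for DIAP2.1.3 (6.57) and ACTC.2.3 (13.6). Single values were those of ITB3 in upstream 2010 replicate 6 (2.18, above), KLC in upstream 2010 replicate 1 (2.39, below) and FRIS.1.2 in downstream 2010 replicate 6 (10900, above).

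The site effect differed between the years in 226 contigs by the interaction test. The difference of 2010 less 2009 was 2.09 for NHRF1, 1.75 for TRMT44.2.2, 1.56 for Ddx17, 1.33 for DIAP2.1.3, 1.30 for ADHX.4.4 and -0.786 for ppp1r15b. The list medians were -0.461 for heat shock and chaperones, -0.426 for ubiquitin and proteasome, -0.627 for ribosomal proteins, -0.941 for cytoskeleton and -1.54 for tropomyosins. With an estimated correlation none of these lists passed (adjusted p = 0.539 for ribosomal proteins and 0.441 for the others). Leaving out downstream 2009 replicates 7 and 8 made the medians -0.137, -0.219, 0.38, -0.0642 and -0.735. Of 100 splits of the animals of each year into 2 sites, 2 called at least 226 contigs, the real one included, and the highest other called 1965. Few splits reached the real count, but another split called several times as many, so this count does not exclude chance. Such a split points to a structure of the samples, and what that structure is was not tested.

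For the site effect 2010, 1 of 100 splits, the real one, called as many as 84, and the highest other called 0. Chance is thus an unlikely source of these calls, within the limit of 100 splits. The count itself was 16 without upstream 2010 replicate 3, 29 with RLE factors and 39 with a lane term, and the splits do not cover this dependence. For the site effect 2009 and the mean over both years edgeR called 0 contigs (4277 and 6429 at an unadjusted p under 0.05; DESeq2 49 and 227, limma-voom 0 each). Any split reaches 0, as 100 of 100 did, so this count decides nothing there. The highest of the other splits called 9689 and 7131. For the year effects, 1 of 100 splits upstream and 1 of 100 downstream called as many as the real 1914 and 14225, and the highest others called 0. By this count chance is an unlikely source of the year effects, within the limit of 100 splits. For age, 1 of 50 called as many as 1258, and the highest other called 71. The age count came from fewer splits and was 0 without downstream 2010 replicate 5. It rests on that animal, so the splits do not exclude chance there.

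The count of the year effect was higher downstream than upstream, 14225 against 1914. Without downstream 2009 replicates 7 and 8 the ratio of the counts was 2.42, between the bounds of 1.5 and 3 set for the test, so the part of these animals cannot be told apart from that of the site. With an age term the counts were 8298 and 1392, a ratio of 5.96, above the bound of 3. Downstream in 2009 7 animals were old and 0 young, so the age term leans on the other groups. This ratio therefore does not settle the part of age. A ratio of counts is not a test of whether the year effects differ between the sites. The interaction, which is such a test, called 226 of 51264 contigs, and 37 with an age term. Across contigs the year effects had a Pearson r of 0.638, and 5 contigs were called in opposite directions. A difference between the sites in what changed from 2009 to 2010 stays open and may be biological, and it was not tested beyond the interaction.

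The medians of the 39 ribosomal protein contigs were below 0 in 2010 at both sites. Downstream 31 contigs were called lower and upstream 0 by edgeR (27 adjusted over the list alone), and the list passed at neither site with an estimated correlation (adjusted p = 0.269 and 0.562). With RLE factors the smaller of the changes, less the median of all contigs, was -1.17. This difference is the same under any size factor, so it decides nothing on the scaling of the libraries. The medians were -1.19 and -1.8 with RLE and -1.19 and -1.76 with TMM factors, and both methods take most contigs as unchanged; a scaling that does not was not tested, so this explanation stays open. Without downstream 2009 replicates 7 and 8 the median downstream was -0.792, with a standard error of 0.25 for the mean over animals. With an age term the medians were -0.957 upstream and -1.43 downstream, with standard errors of 0.36 and 0.423 for the means. The bound set against each explanation was -0.6. The median of -0.792 lies within 1 standard error of it, and that of -1.43 lies beyond it, though these errors are those of the means. Upstream the outcome depends on the error used: -0.957 is within 1 standard error at 0.36, by a narrow margin, and at 0.429 (downstream, no age term), but beyond it at 0.324 (upstream, no age term). The means over animals, to which the errors belong, with an age term were -0.62 upstream and -0.613 downstream, both near the bound. Without downstream 2009 replicates 7 and 8 the mean downstream was -0.467, short of the bound. So the 2 animals and age could each account for part, and for age the case is borderline. A biological difference between the years stays open, as untested.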

How the results depend on the processing

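The fit without downstream 2009 replicates 7 and 8 and the tests in it were chosen after the data were examined; the other alternatives were not. The counts given are contigs called.

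With RLE factors the site effect 2010 had 29 and the interaction 137. With an age term the year effect downstream had 8298 and the interaction 37, and the correlation of the site effects was reversed, at -0.0568. With a lane term the site effect 2010 had 39, the interaction 93 and age 4335. With both terms these were 35 for the site effect 2010, 1059 and 5446 for the year effects upstream and downstream and 67 for the interaction. With only the 2 groups compared the site effect 2010 had 1487 and the year effect upstream 1180. Age had 564 in the animals of 2010 and 13511 with no group term. limma-voom called 14879 for the site effect 2010, 24469 for the year effect downstream, 4070 for the interaction and 8554 for age. DESeq2 called 49, 755 and 227 for the site effects 2009, 2010 and over both years, 3612 for the year effect upstream, 940 for the interaction and 4104 for age. The cause was not tested.

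Without downstream 2009 replicates 7 and 8 the site effect 2010 had 782, the year effect upstream 4420, the interaction 706 and age 3680. List tests then reversed in direction, to lower for the site effects and to higher for the interaction. The adjusted p with the preset correlation was 0.0168, 0.216 and 0.407 for oxidative phosphorylation, ribosomal proteins and cytoskeleton in the site effect 2009. It was 0.177 and 0.0322 for ribosomal proteins and cytoskeleton over both years, and 0.665 for ribosomal proteins in the interaction. An estimated correlation was not run in this fit. The median of oxidative phosphorylation in the site effect 2009 was -0.44 in it, against -0.103. Of 31 list tests called by camera, 0 passed with an estimated correlation. Of 114 calls of named contigs, counted per comparison, 73 passed without replicates 7 and 8. The 10 for age have no fit with an added age term; of the others 63 passed with an age term and 30 with both terms, and of the 10, 3 passed in the animals of 2010. The cause was not tested.

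With each library left out, the counts were 0 to 0 for the site effect 2009 and over both years, 16 to 556 for the site effect 2010, 784 to 3624 and 11631 to 16778 for the year effects, 35 to 840 for the interaction and 0 to 2580 for age. The site effect 2009 without old animals was not run, since 1 downstream animal was left. Depth limits RhPVgp2 in 2010, where 25 and 23 reads were counted per group.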

Other observations

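The zinc finger and RNA splicing names, the classes by prefix, their correlations and the lane tests were chosen after the data were examined.

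Contigs with zinc finger names, 84 contigs under 48 names, were counted in the year effects. Upstream 36 fell and 1 rose, with a median of -0.80, and downstream 59 fell and 2 rose, with a median of -0.93. ZEB2 fell by 1.16 upstream (SE 0.143) and by 1.30 downstream (SE 0.143). Over the alternatives 14 to 52 fell upstream and 20 to 66 downstream. The list was drawn up after its members were seen, so no list test is given for it, nor for the splicing names. Of 17 RNA splicing names 2 rose upstream, and 3 rose and 5 fell downstream.

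Lane was called for 3 of 51264 contigs. Between lanes 1 and 2 and lanes 3 and 4, 16 libraries each, CAPSD had 26.5 and 368 CPM, H 13.0 and 183 CPM, and VGA 22.5 and 320 CPM, with folds of 13.9, 14.1 and 14.2. The lane pairs did not overlap: the highest CAPSD value in lanes 1 and 2 was 63.3 CPM and the lowest in lanes 3 and 4 was 168 CPM. For H these were 30.4 and 82.8 CPM, and for VGA 51.5 and 147 CPM. Each group was spread over the lanes, so these levels followed lane and are not read as levels of mussel transcripts. Their source was not tested.

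Contigs with locus tags of THAPSDRAFT or PHATR type carry the prefix of a diatom gene model. The prefix names the best-matching model, not the organism of origin. Their 17 contigs summed to a median of 24 CPM upstream and 11.7 CPM downstream in 2009, and to 4.47 and 4.48 CPM in 2010. Of 6 tested, 5 were lower in 2010 upstream and 4 downstream. The 29 contigs with ciliate prefixes had summed medians of 370, 381, 268 and 263 CPM, and the 11 with green alga prefixes 23.3, 23, 22 and 23.2 CPM. These sums, also used below, weight the abundant contigs. Contig by contig, the 24 tested ciliate-prefix contigs had a median log2 difference downstream over upstream of 1.71 in 2009 and 1.77 in 2010, with 0 called. For the 11 green alga contigs it was -0.147 and -0.167, with 0 called.

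RhPVgp2 fell from 2009 to 2010 at both sites. The 2009 median lay above the floor of 3 counts, which was higher than the 2010 median, by a log2 value of 3.24 in lanes 1 and 2 and 7.07 in lanes 3 and 4. These are lower bounds of the year difference in each lane pair, which argues against lane, and the floor of 3 counts in the shallowest 2010 library was 0.0134 of the 2009 median, which argues against depth. Over the 16 animals of 2009 RhPVgp2 and the diatom-prefix contigs had a Spearman rho of 0.662 (two-sided permutation p = 0.00654, adjusted p = 0.0327 over 5 relations) and a Pearson r of 0.661 (permutation p = 0.00509, adjusted p = 0.0254; r of 0.661 without the 2 animals farthest from the median). Within sites r was 0.725 upstream (exact p = 0.0513; 0.492 without 2 animals) and 0.310 downstream (exact p = 0.441), and rho was 0.571 (exact p = 0.151) and 0.333 (exact p = 0.428), so with 8 animals per site the relation did not pass 0.05 within either site, which leaves it open. With the ciliate-prefix contigs over the same 16 animals, rho was 0.247 (permutation p = 0.355; 0.0637 without 2 animals) and r was 0.350 (permutation p = 0.184), so the relation did not pass 0.05 for that class. RNA of ingested or attached organisms may be a source of RhPVgp2 reads, and an infection of the mussels cannot be told apart from it.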
